A study of Bos taurus with 8 samples.

How the data were processed

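Endometrium of the uterine horn on the side of the corpus luteum was sampled on day 7 from 8 cows, per the labels, 4 given 0 mM and 4 given 5 mM methylglyoxal in 25 mL per horn on day 1. Each sample is a different cow, per the labels. RNA was extracted with a Qiagen RNeasy Plus Universal kit and amplified with Cy3-labelled CTP in an Agilent Quick Amp one-colour reaction with spike-in RNA, per the labels' protocols. The arrays were of Agilent design 023647, and probe coordinates are on the bovine build HGSC Btau_3.1, per the file headers. The deposited values used here are spot intensities on a linear scale, which Feature Extraction made by subtracting the background and removing spatial and multiplicative trends, without scaling between arrays, per the file headers. The software version is 11.5.1.1 per the file headers and 10.5.1.1 per the submitters' processing notes.

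The series' deposited value table holds log2 values. Over all 43653 noncontrol probes its columns correlated with log2 processed intensities that had been shifted to each array's 75th percentile and centred per probe on the median of the 8 arrays, with Pearson's r of at least 0.999986 across probes, so its scale, centring and direction were found. The largest single difference was 0.46. The column medians were -0.016, -0.023, 0.00090 and -0.0062 for 0 mM replicates 1 to 4 and 0.13, -0.0049, -0.011 and 0.013 for 5 mM replicates 1 to 4. This table was used only as an alternative.

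Control spots and spots with a scanner outlier mark were left out, and log2 processed intensities were averaged over the spots of a probe. The log2 of the array's 75th percentile, taken over all noncontrol spots with marked ones included, was then subtracted. A probe was tested if it was well above background on at least 4 of the 8 arrays, whatever their group, which left 31108 probes, with 461 values missing. Gene names came from the files and were updated with a RefSeq gene table of assembly ARS-UCD2.0. Of the 43653 probes, 34982 had a symbol, 22033 of them through an accession, 11170 by name or gene identifier, 413 through a synonym and 1366 as the file gave it. No genome of the build of the array was used here, so exons and untranslated regions are not given. Among tested probes 25750 had a symbol, for 13079 symbols. Where a gene had several probes, the one with the highest mean over all arrays was taken.

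The groups were compared with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. Probes at an unadjusted p under 0.05 and at least 2-fold apart were counted as well. The median standard error of a log2 difference was 0.24. Gene lists for functions and for cell types of an endometrial biopsy, 39 with at least 5 measured genes, were tested with limma's camera at a preset inter-gene correlation of 0.01 over 12937 genes, 142 genes with a missing value being left out, and adjusted over the 39 lists. The same lists were tested with an estimated correlation, with fry and, as a choice made after seeing the data, with an exact two-sided permutation test of list means over the 70 arrangements of the cows, whose smallest p is 0.0286. A gene not well above background on any array of a group has only a bound there. Its fold is given as at least the mean log2 level of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the probe's own signal. This bound holds for the processed signals and not under another background correction.

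The groups, tests, lists, main alternatives and the rule for named genes were fixed before the data were examined. By that rule, up to 12 genes in each direction were the largest changes past the adjusted threshold without overlap between groups, filled up with the lowest unadjusted p among genes at least 2-fold apart without overlap. GLO1, HAGH, AGER and the 3 lowest-p members of each list were named whatever their values, and symbols beginning with LOC were not named. The rule gave 137 genes, and the results of 5 of them are not reported here. The alternatives fixed in this way were quantile normalization, a median shift, normexp with an offset of 50, no filter, a filter on all 8 arrays, eBayes with trend and robust settings, array weights, the deposited value table, an adjusted threshold of 0.1, the mean over a gene's probes, slide as a block and within slides, a replicate block and leaving out each cow. Slide 1 held replicate 1 of both groups, slide 2 held 0 mM replicates 2 and 3 with 5 mM replicate 2, and slide 3 held 0 mM replicate 4 with 5 mM replicates 3 and 4. Chosen after seeing the data were marker means of smooth muscle, epithelium or immune cells as a covariate, leaving out the 3 arrays with the highest smooth muscle means, and leaving out probes that share 8 bases with the telomere repeat.

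The test was tried on simulated data with 31108 probes and the spread of the 8 arrays, 200 probes being changed at a time. It recovered 0% of them at 1.5-fold, 15% at 2-fold, 68.5% at 4-fold and 84% at 8-fold. With the spread of the arrays without 5 mM replicate 1, these shares were 0%, 38.5%, 80% and 91.5%. False calls numbered 0, 2, 8 and 8 with the first spread and 0, 6, 13 and 6 with the second. Probes were drawn independently, whereas probes of the real arrays can vary in step, so these shares describe the simulated setting only. In a simulated shift of -0.50 in the interferon list, with genes drawn independently, camera called that list and no other. The estimated correlation within the real list was 0.385, so this does not show how often camera calls correlated lists by chance. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.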

Results

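Endometrial tissue was biopsied on day 7 after standing estrus from 8 cows whose uterine horns had each received 25 mL of fluid on day 1. The fluid held methylglyoxal, a reactive dicarbonyl by-product of glycolysis that glycates proteins, at 0 mM in 4 cows and at 5 mM in the other 4. Total RNA from each biopsy was labelled with Cy3 and hybridised to its own one-colour Agilent bovine array, so that each value comes from a separate animal. The arrays carried 43653 noncontrol probes, and between 68.3% and 73.2% of them were well above background on each array. The 75th percentile of the processed signal lay between 1032 and 1456 intensity units, and no spot was saturated. The number of arrays limits the precision of every comparison. Values below are log2 signals relative to the 75th percentile of the same array, differences are 5 mM minus 0 mM, and a group value is a mean ± SD over 4 cows.

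The comparison asked which endometrial transcripts differed on day 7 between cows given methylglyoxal and cows given the fluid without it. No transcript passed the multiple-testing threshold. Of the genes with the lowest unadjusted p, those with higher values in the 5 mM group included LAP, which encodes the lingual antimicrobial peptide (a beta-defensin), and those with lower values included chemokine and B cell genes. LAP was -5.35 ± 0.27 in cows given 5 mM and -7.44 ± 0.70 in cows given 0 mM, a difference of 2.10 ± 0.34 (SE). Its probe was well above background on 1 array of the 0 mM group and 4 of the 5 mM group, so the lower level lies near background, and with normexp the difference was 0.54. The interferon-induced chemokine genes CXCL9, CXCL10 and CXCL11, whose products attract T cells, differed by -2.21 ± 0.67, -1.43 ± 0.37 and -1.33 ± 0.26. MS4A1, which encodes a B cell surface protein, was well above background on all 4 arrays of the 0 mM group and on 0 of the 5 mM group, a level at least 2.93-fold lower. With normexp its difference was -0.63, so this bound depends on the background correction.

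In the limma test with Benjamini-Hochberg adjustment, 0 of 31108 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.913. At an unadjusted p under 0.05 there were 595 probes, against 1555 that chance alone would give. Of these, 166 probes with 122 gene symbols were at least 2-fold apart, 63 higher and 103 lower in the 5 mM group. This count was 327 without 0 mM replicate 1, 557 without 5 mM replicate 2 and 409 without 5 mM replicate 4. With slide as a block it was 263, and within slides 2 and 3, where 1 of the groups is a single array, it was 475 and 538. The 4 values of one group lay wholly above the 4 of the other for 479 probes (1.54%), where chance gives 2.86%.

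The 24 genes named by rank, 12 in each direction, were chosen for being at least 2-fold apart with no overlap between groups. None passed the adjusted threshold. Besides LAP, whose probe lies on chromosome 27, 7408532 to 7408591 of the HGSC Btau_3.1 build, the higher values included AFMID, which encodes the arylformamidase of the kynurenine pathway (1.72 ± 0.33, unadjusted p = 0.000904). CMSS1 (1.23), CCER2 (1.51), SYT12 (2.02), the transcription factors GATA4 (2.06) and STAT5A (1.69) and the photoreceptor gene PCARE (1.71) followed. These genes and AFMID varied in step across the 8 arrays, and the probes of 6 of the 12 higher genes, among them AFMID, CMSS1, CCER2, SYT12 and GATA4, share at least 8 bases in a row with the telomere repeat CCCTAA, as do 79 of the 31108 tested probes. The second AFMID probe, which matches the repeat by 4 bases, differed by -0.052, and the second STAT5A probe by -0.071. The other higher genes included the receptor gene GPR182 (1.12), NNMT, which encodes nicotinamide N-methyltransferase (1.70 ± 0.45) and was well above background on 1 array of the 0 mM group and 3 of the 5 mM group, and MS4A13 (1.30 ± 0.36), whose second probe differed by 3.52 (unadjusted p = 0.000123), against 0.00734 for the first and 0.000283 for LAP.

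The 12 genes with lower values included several of lymphocytes and other leukocytes. GIMAP5, a lymphocyte GTPase gene, differed by -1.54 ± 0.32 (unadjusted p = 0.00121), LCP1, which encodes the leukocyte actin-bundling protein L-plastin, by -1.03 ± 0.28, and BATF, a transcription factor of lymphocytes, by -1.40 ± 0.38. The probes of CXCL9, CXCL10 and CXCL11 lie close together on chromosome 6, starting at 94105453, 94129412 and 94147023, and their unadjusted p values were 0.0108, 0.00437 and 0.000991. The second CXCL10 probe gave -1.57. Besides the leukocyte and chemokine genes, QRFPR, a neuropeptide receptor gene, differed by -2.06 ± 0.40, ACP2, a lysosomal acid phosphatase gene, by -1.28 ± 0.35, and GABRG3, a GABA receptor subunit gene, by -1.79 ± 0.50. Of the 4 arrays of the 5 mM group, GABRG3 was well above background on 1, and CXCL11 and BATF on 2 each. The histone gene HIST1H2AH and the sulfotransferase gene CHST8 were not well above background on any array of the 5 mM group and were at least 1.74-fold and 2.46-fold lower there. With normexp 13 of the 24 genes named by rank had differences smaller by over 1.5 times, among them NNMT at 0.32, CHST8 at -0.071, HIST1H2AH at -0.21, CXCL11 at -0.24, BATF at -0.34, GABRG3 at -0.39 and MS4A1 at -0.63.

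**Figure D1:**
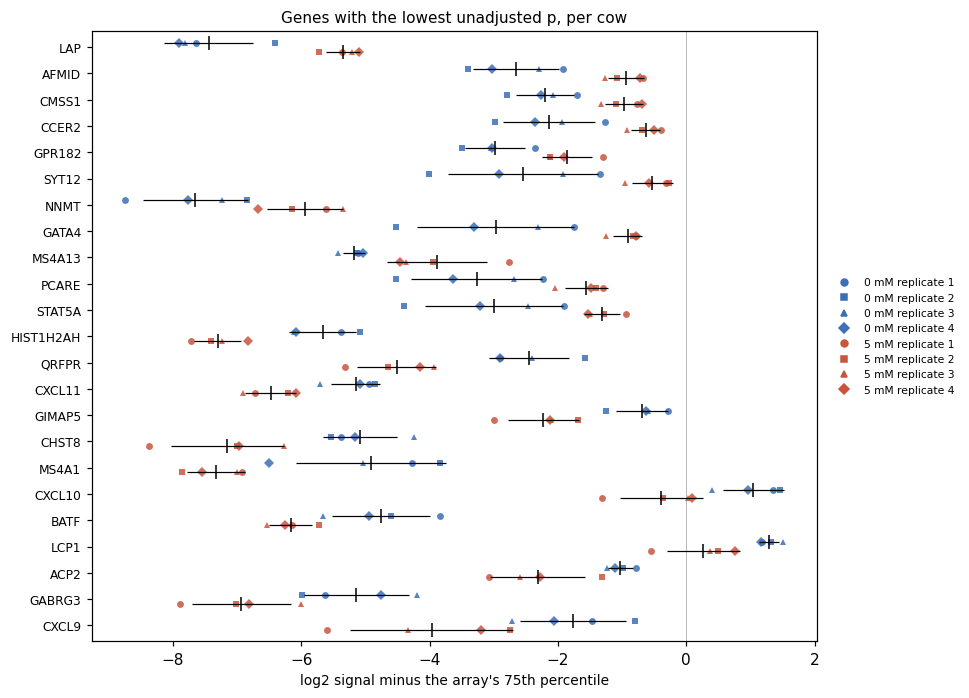
Log2 signal minus the array's 75th percentile (horizontal axis) of 23 of the 24 genes with the lowest unadjusted p, where each point is 1 cow (blue 0 mM, red 5 mM, marker shape the replicate number), the short vertical line is the mean of 4 cows and the bar is 1 SD on each side. Blue and red points do not overlap for any of these genes, which were chosen for that, and none passed the adjusted threshold.

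Lists of immune genes lay lower in the 5 mM group. All 20 measured antigen presentation genes were lower, with a median difference of -0.72, and so were 33 of 38 interferon-stimulated genes (median -0.59) and 32 of 43 cytokine, chemokine and NF-kB target genes (median -0.38). Leukocyte markers were lower as well, in 17 of 21 T and NK cell markers (median -0.60), 9 of 9 B and plasma cell markers (median -0.98) and 20 of 21 macrophage and dendritic cell markers (median -0.42). In the camera test with a preset correlation, the adjusted p was 1.08e-08 for antigen presentation, 1.05e-08 for the interferon list, 4.92e-06 for the cytokine list, 6.55e-05 for T and NK cells, 0.000361 for B and plasma cells and 6.55e-05 for macrophages and dendritic cells. With an estimated correlation, no list of the 39 passed, and the adjusted p was 0.655 for each of these 6.

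In the cytokine list all 4 cows given 5 mM lay below the 4 given 0 mM, while in the antigen presentation and interferon lists the groups overlapped. The separation in the cytokine list was narrow, with -0.027 on 5 mM replicate 2 and -0.015 on 0 mM replicate 1. The antigen presentation mean was -0.50 ± 0.50 in the 5 mM group and 0.50 ± 0.35 in the 0 mM group, relative to the mean of the 8 arrays (exact permutation p = 0.0571, two-sided). For the interferon list the means were -0.26 ± 0.40 and 0.26 ± 0.41 (exact permutation p = 0.143), and for the cytokine list -0.21 ± 0.25 and 0.21 ± 0.26 (exact permutation p = 0.0286, the smallest that 4 against 4 can give). Over the 39 lists, no such p passed adjustment. The antigen presentation list included ERAP1 (-0.62), BOLA-DRA (-0.53) and NLRC5 (-0.95), of which NLRC5 has a second probe with the other sign. BOLA-DRA encodes an MHC class II chain and ERAP1 trims peptides for MHC class I. The interferon list included IFITM1 (-0.65), IFI6 (-0.64) and OAS1Y (-0.74), and the cytokine list was led by CXCL11, CXCL10 and CXCL9. Adjusted over the list alone, 1 cytokine gene, CXCL11, passed (adjusted p = 0.0426), and no antigen presentation or interferon gene did. Adjusted over all probes, none passed.

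The leukocyte lists were led by ICOS (-1.26), CD5 (-1.04) and CD3G (-1.01) for T and NK cells, MS4A1 (at least 2.93-fold lower, but -0.63 with normexp), TNFRSF13C (-0.98) and BLK (-0.98) for B and plasma cells, and FCGR3A (-1.07), C1QC (-1.18) and C1QA (-1.03) for macrophages and dendritic cells. Adjusted over the list alone, 2 B and plasma cell genes passed, MS4A1 and TNFRSF13C, the receptor for a B cell survival factor, and no gene of the other leukocyte lists did. The median difference of the antigen presentation list was -0.68 with slide as a block and -0.75, -0.46 and -0.44 within slides 1, 2 and 3. For the interferon list these values were -0.50 with slide as a block and -0.32, -0.46 and -0.33 within slides 1, 2 and 3. For the cytokine list they were -0.26 with slide as a block and -0.00051, -0.34 and -0.33 within slides 1, 2 and 3. The T and NK cell medians were -0.64 with slide as a block and -0.94, -0.41 and -0.36 within slides 1, 2 and 3, those of B and plasma cells -0.92 with slide as a block and -0.56, -1.42 and -0.36 within slides 1, 2 and 3, and those of macrophages and dendritic cells -0.37 with slide as a block and 0.32, -0.34 and -1.04 within slides 1, 2 and 3. Slide 1 holds 1 array of each group, slide 2 a single array of 5 mM and slide 3 a single array of 0 mM, so no call is made within a slide. Without 5 mM replicate 1 the median was -0.37 for antigen presentation and -0.24 for T and NK cells. Without 0 mM replicate 2 it was -0.38 for the interferon list and -0.63 for B and plasma cells, and the latter was -0.44 without 5 mM replicate 2. The macrophage and dendritic cell median was -0.89 without 0 mM replicate 1, -0.26 without 0 mM replicate 4 and -0.27 without 5 mM replicate 3. In each of these fits without 1 cow the adjusted p stayed under 0.05 in the camera test with a preset correlation.

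**Figure D2:**
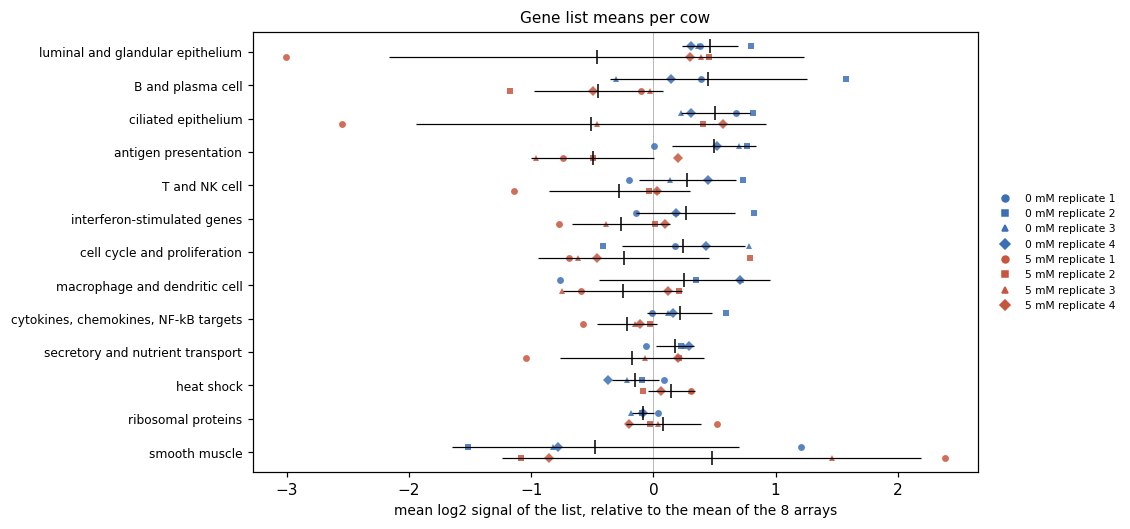
Mean log2 signal of the 13 gene lists past the preset-correlation threshold (horizontal axis, relative to the mean of the 8 arrays), where each point is 1 cow (blue 0 mM, red 5 mM, marker shape the replicate number), the short vertical line is the mean of 4 cows and the bar is 1 SD on each side. The point of 5 mM replicate 1 at -3.00 stands apart in the luminal and glandular epithelium list, and the smooth muscle list spans -1.51 to 2.38.

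The biopsies also differed in the markers of epithelium and muscle, with 1 cow far from the rest. The luminal and glandular epithelium mean was -3.00 on 5 mM replicate 1 and between 0.30 and 0.80 on the other 7 arrays, and the ciliated epithelium mean was -2.54 against -0.46 to 0.82. Smooth muscle markers were at 2.38 on that array, at 1.46 on 5 mM replicate 3 and at 1.21 on 0 mM replicate 1, and between -1.51 and -0.78 on the rest. All 20 epithelium markers (median -1.02, adjusted p = 4.6e-05) and all 17 ciliated cell markers (median -0.93, adjusted p = 8.26e-07) were lower in the 5 mM group, and 13 of 14 smooth muscle markers were higher (median 1.09, adjusted p = 0.00843) in the camera test with a preset correlation. With an estimated correlation the adjusted p was 0.655 for each. Without 5 mM replicate 1 the epithelium median was -0.074 (adjusted p = 0.349), the ciliated median -0.33 (adjusted p = 0.000368) and the smooth muscle median 0.39 (adjusted p = 0.408).

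The smooth muscle list also lost its adjusted p under 0.05 without 0 mM replicate 2, at 0.70, and without 5 mM replicate 3, at 0.76, and its median was 1.71 without 0 mM replicate 1 and 1.71 without 5 mM replicate 2. The epithelium medians were -1.03 with slide as a block and -3.70, -0.15 and 0.0087 within slides 1, 2 and 3. Those of ciliated epithelium were -1.03 with slide as a block and -2.55, -0.076 and -0.22 within slides 1, 2 and 3, and those of smooth muscle 0.85 with slide as a block and 1.23, 0.032 and 1.23 within slides 1, 2 and 3. With array weights the smooth muscle median was 0.51 (adjusted p = 0.119). The epithelium markers with a low p included KRT7 (-1.35) and KRT19 (-0.86), the ciliated ones CCDC40 (-1.41), CAPS (-0.71) and CCDC39 (-0.78), and the smooth muscle ones CASQ2 (-1.20), PLN (1.45) and SYNM (1.52), of which CASQ2 was the 1 lower marker of the list and was well above background on 1 array of the 5 mM group. Without 5 mM replicate 1, KRT19 was at -0.25. Over all settings, single slides included, KRT7 ranged from -1.73 to 0.043, PLN from 0.27 to 2.03 and SYNM from -0.27 to 2.16.

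Of the secretory and nutrient transport genes of the receptive endometrium, 36 of 51 were lower (median -0.31, adjusted p = 0.0346 with the preset and 0.655 with an estimated correlation), among them IGFBP2 (-1.48), which encodes an insulin-like growth factor binding protein, while LPL, the lipoprotein lipase gene (1.17), and FABP5 (0.52) were higher. Its mean was -1.04 on 5 mM replicate 1, the array with the low epithelium markers, and the median was -0.034 without that array (adjusted p = 0.459). The call also ended without 0 mM replicate 2, 3 or 4, at medians of -0.28, -0.30 and -0.24, and with array weights, at -0.13. The secretory medians were -0.34 with slide as a block and -0.68, -0.074 and -0.21 within slides 1, 2 and 3. Cell cycle genes were lower in 38 of 44 cases (median -0.50, adjusted p = 0.000121 with the preset and 0.655 with an estimated correlation), led by CCNE2 (-0.50), ASPM (-1.85) and KIF11 (-1.39). Of these, ASPM and KIF11 were each well above background on 1 array of the 5 mM group. The mean of the cell cycle list was 0.79 on 5 mM replicate 2 and between -0.69 and -0.46 on the other arrays of that group, and its median was 0.58 within slide 2, -0.96 within slide 3, -0.72 within slide 1 and -0.38 with slide as a block. Without 0 mM replicate 3 it was -0.30 (adjusted p = 0.0557), without 5 mM replicate 2 it was -0.84, and without 5 mM replicate 3 it was -0.33.

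Ribosomal protein genes were higher in 56 of 57 cases by a median of 0.15 (adjusted p = 1.84e-06 with the preset and 0.655 with an estimated correlation), including RPL13 (0.42) and RPS24 (0.41). Their mean was 0.52 on 5 mM replicate 1 and between -0.20 and 0.035 on the rest, and the median was 0.021 without that array (adjusted p = 0.546), 0.24 without 5 mM replicate 4 and 0.011 after quantile normalization (adjusted p = 0.457). It was 0.17 with slide as a block and 0.49, 0.12 and -0.014 within slides 1, 2 and 3, and 0.041 (adjusted p = 0.0944) with array weights. Other probes of RPL13 lay between -0.040 and 0.59, and those of RPS24 at 0.40 and -0.51. Heat shock genes were higher in 18 of 22 cases by a median of 0.12 (adjusted p = 0.00459 with the preset and 0.655 with an estimated correlation), including HSPA6 (1.44), DNAJB1 (0.40) and HSP90AA1 (0.30). HSPA6 was at -4.10 on 5 mM replicate 4 and between -6.14 and -5.85 on the others of that group. Its difference ranged from 0.35 to 2.86 over all settings, single slides included. Without 0 mM replicate 4 the median of the heat shock list was 0.074 (adjusted p = 0.0942), without 0 mM replicate 1 it was 0.24 and without 5 mM replicate 2 it was 0.20. The heat shock median was 0.13 with slide as a block and 0.059, 0.064 and 0.35 within slides 1, 2 and 3. Over the mean of a gene's probes it was 0.12 (adjusted p = 0.0797).

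No gene known to remove methylglyoxal passed the threshold. GLO1 (chromosome 23, probe at 12988895 to 12988954), which encodes glyoxalase I, was 0.66 ± 1.67 with 5 mM and 0.98 ± 1.18 with 0 mM, a difference of -0.32 ± 0.89 (SE). HAGH, the glyoxalase II gene, differed by 0.056 ± 0.13, and AGER, the receptor for advanced glycation end products, by -0.10 ± 0.28. The methylglyoxal and aldehyde detoxification list had a median of 0.020 over 22 genes (adjusted p = 0.881), with ALDH7A1 (0.26), ADH5 (0.27) and AKR1B10 (-0.74) at the lowest p. Receptors and ligands of advanced glycation end products had a median of 0.012 over 19 genes (adjusted p = 0.998), with SCARB1 (-0.61), PRKCSH (0.29) and HMGB1 (0.16). For NRF2 targets and glutathione genes, which answer electrophilic stress, the median was -0.037 over 32 genes (adjusted p = 0.935), with the catalase gene CAT (0.31), GSTM1 (0.38) and MGST1 (-0.26). Without 5 mM replicate 1 the NRF2 median was 0.089 (adjusted p = 0.043 at the preset correlation). Without any other cow it was between -0.11 and 0.014, not past the threshold. With an estimated correlation over all cows the adjusted p of this list was 0.998. The fit without 5 mM replicate 1 gave -0.21 for AKR1B10, 0.054 for PRKCSH and 0.018 for HMGB1. Other probes of HMGB1 lay between -0.21 and 0.085. GLO1 was 0.19 without 0 mM replicate 1 and 0.20 without 5 mM replicate 3, AGER was 0.077 without 5 mM replicate 2, and HAGH was -0.012 without 5 mM replicate 4.

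The other stress and inflammation lists did not pass the camera test with a preset correlation, although some passed it under an alternative, and none passed with an estimated correlation. The unfolded protein and integrated stress response list had a median of -0.15 over 31 genes (adjusted p = 0.0515), with TRIB3 (-0.60), ASNS (0.30) and SHMT2 (-0.33). With an estimated correlation the adjusted p was 0.655. Its mean was -0.45 on 5 mM replicate 1, against at most 0.15 and at least -0.00023 on the other 3 arrays of that group, and the median without that array was -0.014. The median was -0.16 with slide as a block and -0.43, 0.033 and -0.0030 within slides 1, 2 and 3. At the preset correlation the list passed after quantile normalization, at -0.12 (adjusted p = 0.0176), with the block (adjusted p = 0.0238), with normexp, at -0.072 (adjusted p = 0.0359), and with either other filter. It also passed without 0 mM replicate 2, at -0.17 (adjusted p = 0.0395), without 0 mM replicate 4, at -0.12 (adjusted p = 0.0391), and without 5 mM replicate 3 or 4, at -0.15 and -0.20. It did not pass without 0 mM replicate 1 or 3, at -0.14 and -0.083, or without 5 mM replicate 1 or 2, at -0.014 and -0.14. Immediate early genes had a median of -0.34 over 22 genes (adjusted p = 0.0593), with NR4A2 (-0.70), JUNB (-0.64) and IER2 (-0.40). With an estimated correlation the adjusted p was 0.655 as well. At the preset correlation they passed after a median shift, at -0.28 (adjusted p = 0.0339), with normexp, at -0.28 (adjusted p = 0.0146), with array weights, at -0.24 (adjusted p = 0.0137), and with either other filter. Their median was -0.34 with slide as a block and 0.0044, -0.54 and -0.036 within slides 1, 2 and 3, and the adjusted p with the block was 0.0508. Without 0 mM replicate 1 or 4 it was -0.47 (adjusted p = 0.0128) and -0.37 (adjusted p = 0.0156), and without 5 mM replicate 1 or 3 -0.21 (adjusted p = 0.043) and -0.35 (adjusted p = 0.0121). The immediate early list did not pass without 0 mM replicate 2, at -0.17 (adjusted p = 0.727), or 3, at -0.29 (adjusted p = 0.0665). Nor did it without 5 mM replicate 2, at -0.27 (adjusted p = 0.45), or 4, at -0.33 (adjusted p = 0.182). Toll-like receptor genes had a median of 0.015 over 19 genes (adjusted p = 0.998), with LY96 (-0.33), IRAK4 (0.16) and LBP (0.63). Acute phase, complement and antimicrobial genes had a median of 0.0051 over 33 genes (adjusted p = 0.903), with LAP, BPI (-1.29), which encodes a bactericidal protein, and PIGR (2.11), the polymeric immunoglobulin receptor gene. Adjusted over the list alone, LAP passed (adjusted p = 0.00935). The p53, apoptosis and senescence list had a median of -0.084 over 34 genes (adjusted p = 0.116), with PMAIP1 (-0.44), PERP (-1.82) and CYCS (-0.33). With normexp it was -0.064 (adjusted p = 0.0359), and with no filter the adjusted p was 0.0366. Hypoxia and angiogenesis genes had a median of -0.0012 over 24 genes (adjusted p = 0.735), with TEK (-0.43), EPAS1 (-0.31) and PGF (-1.27). The fit without 5 mM replicate 1 gave 0.0082 for LBP, -0.57 for PERP and -0.40 for PGF, and the second IRAK4 probe had the other sign. Without the 3 arrays with the highest smooth muscle means, 5 arrays remained, 0 mM replicates 2, 3 and 4 and 5 mM replicates 2 and 4. In this fit at the preset correlation, the acute phase list was at -0.19 (adjusted p = 0.0405) and the immediate early list at -0.34 (adjusted p = 3.49e-06). With an estimated correlation over all cows the adjusted p was 0.973 and 0.655 for these lists.

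Metabolic, matrix and hormone lists did not pass it either, again apart from some alternatives. Glycolysis genes had a median of 0.014 over 24 genes (adjusted p = 0.903), with PDK1 (0.33), SLC16A3 (-0.96) and PFKFB3 (-0.33). Other probes of SLC16A3 differed by 0.22, -0.92 and -0.45. Oxidative phosphorylation genes had a median of -0.021 over 47 genes (adjusted p = 0.549), with SDHC (-0.23) and NDUFB10 (0.45). NDUFS1 (1.14) also had a low p, but its named probe lacked a value on 5 mM replicate 2, so it was left out of the test of the list. After quantile normalization the median of this list was -0.081 (adjusted p = 0.0265). Of the 5 probes of NDUFS1, all but the named one were lower with 5 mM, by -0.25 to -0.089. Cholesterol and fatty acid synthesis genes had a median of 0.11 over 26 genes (adjusted p = 0.125), with ACACA (0.70), MVK (0.75) and FADS2 (0.38). With an estimated correlation the adjusted p of this list was 0.655. Its median was 0.12 with slide as a block and 0.072, 0.32 and 0.096 within slides 1, 2 and 3, and it passed at the preset correlation with the block (adjusted p = 0.0203), with array weights, at 0.12 (adjusted p = 0.0415), without 5 mM replicate 1, at 0.12 (adjusted p = 0.043), and without 5 mM replicate 4, at 0.14 (adjusted p = 0.0288). Without any other cow it was between 0.065 and 0.17, not past the threshold. Collagen and matrix genes had a median of 0.076 over 35 genes (adjusted p = 0.735), with FBLN2 (-0.62), THBS2 (0.44) and COL6A2 (0.64). Leaving out 0 mM replicate 3 put them at 0.17 (adjusted p = 0.0306). Without any other cow they lay between -0.076 and 0.14, not past the threshold. With an estimated correlation over all cows their adjusted p was 0.974. Metalloproteinases and their inhibitors had a median of -0.14 over 22 genes (adjusted p = 0.346), with PLAUR (-0.78), MMP28 (-1.00) and MMP11 (-0.50). Without 0 mM replicate 1 they were at -0.24 (adjusted p = 0.0392). Leaving out any other cow put them between -0.20 and -0.029, not past the threshold. With an estimated correlation over all cows the adjusted p was 0.799. TGF-beta targets had a median of 0.061 over 19 genes (adjusted p = 0.735), with INHBA (0.97), TGFB1 (-0.29) and FST (-1.02). The prostaglandin, oxytocin and luteolysis list had a median of -0.14 over 18 genes (adjusted p = 0.38), with PTGS2 (-0.75), PTGIS (0.53) and HPGD (-0.77). Steroid receptor and metabolism genes had a median of 0.031 over 19 genes (adjusted p = 0.903), with HAND2 (-0.73), PGRMC2 (0.35) and ESR1 (0.37). Clock genes had a median of 0.097 over 15 genes (adjusted p = 0.197), with HLF (0.72), CLOCK (0.19) and NR1D2 (0.32). The clock median without 0 mM replicate 4 was 0.17 (adjusted p = 0.0495). Without any other cow it was between 0.047 and 0.14, not past the threshold. The fit without 5 mM replicate 1 gave -0.25 for HPGD and 0.064 for NR1D2. The fit without the 3 arrays with the highest smooth muscle means used only 5 arrays. At the preset correlation it put cholesterol and fatty acid synthesis genes at 0.15 (adjusted p = 0.0103) and collagen and matrix genes at -0.15 (adjusted p = 0.000525). The median, the mean and the direction of the test were not all of the same sign for the methylglyoxal, glycation receptor, toll-like receptor, acute phase, glycolysis and steroid lists.

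Markers of the remaining cell types did not pass the camera test, although some passed it under an alternative. Stromal fibroblast markers had a median of 0.032 over 13 genes (adjusted p = 0.948), with HAND2 (-0.73), DPT (1.59) and PDGFRA (0.65). Endothelial markers had a median of -0.24 over 14 genes (adjusted p = 0.294), with TEK (-0.43), PECAM1 (0.41) and LYVE1 (1.05). Their median was -0.27 with slide as a block and -0.28, -0.27 and -0.15 within slides 1, 2 and 3, with an adjusted p of 0.0203 with the block and 0.799 with an estimated correlation and no block. Without 5 mM replicate 1 it was -0.074. Squamous epithelium markers had a median of -0.18 over 7 genes (adjusted p = 0.473), with KRT4 (0.48), KRT6A (-0.69) and KRT10 (-1.08). Neutrophil markers had a median of -0.0052 over 12 genes (adjusted p = 0.735), with CATHL5 (-1.28) and ELANE (0.67). Mast cell and eosinophil markers had a median of -0.14 over 10 genes (adjusted p = 0.448), with GATA2 (-0.15), FCER1A (-0.41) and CCR3 (-0.43). Their median without 0 mM replicate 1 was -0.32 (adjusted p = 0.026). Without any other cow it was between -0.20 and -0.032, not past the threshold. Erythrocyte and platelet markers had a median of 0.085 over 7 genes (adjusted p = 0.903), with HBA (1.02), AHSP (-0.24) and HBB (1.31). Adipocyte markers had a median of 0.45 over 7 genes (adjusted p = 0.287), with PCK1 (0.70), FABP4 (2.18) and CIDEA (0.48). Without 5 mM replicate 1 the median was -0.0036 (adjusted p = 0.782). Over all settings, single slides included, FABP4 ranged from -0.69 to 3.18. Schwann cell and neuron markers had a median of -0.55 over 12 genes (adjusted p = 0.122), with CDH19 (-2.06) and STMN2 (-2.94). With normexp their median was -0.35 (adjusted p = 0.0359), and with no filter -0.41 (adjusted p = 0.0483). Without 5 mM replicate 1 it was 0.0080 (adjusted p = 0.418). STMN2 was at -8.37 on that array and between -1.71 and -0.37 on the others of its group. With an estimated correlation over all cows the adjusted p of this list was 0.655. The fit without 5 mM replicate 1 gave -0.13 for KRT10, -0.18 for KRT6A, 0.13 for PDGFRA, -0.11 for CCR3 and -0.0036 for CIDEA. HBB was 0.41 without 5 mM replicate 4, CCR3 was -0.0025 without 0 mM replicate 2, and the second PCK1 probe had the other sign. Other probes of CIDEA differed by -0.58, 0.48 and -0.095. Without the 3 arrays with the highest smooth muscle means, the fit used only 5 arrays. At the preset correlation it put erythrocyte and platelet markers at 0.074 (adjusted p = 0.00303) and endothelial markers at -0.16 (adjusted p = 0.0346). Mast cell and eosinophil markers were at -0.22 (adjusted p = 0.0377) and stromal fibroblast markers at -0.14 (adjusted p = 0.049). With an estimated correlation over all cows the adjusted p was 0.983 for erythrocytes and platelets, 0.799 for mast cells and eosinophils and 0.998 for fibroblasts. Outside the lists named above with a passing gene, no list had a gene past 0.05 when adjusted over the list alone.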

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

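In this part, the test with the immune cell marker mean was set before its result was seen, and all other tests, the splits of the arrays included, were chosen after.

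In 8 of 78 groups of 4 list means, and in 14 of 263 groups of 4 gene values, 1 cow lay far from the other 3 of its group (by Dixon's criterion at the 95% level). Chance gives about 1 in 20, or 3.9 and 13.2 groups. For 5 mM replicate 1 these were the list means of luminal and glandular epithelium (-3.00), T and NK cells (-1.14), the p53 list (-0.49) and the clock list (0.30). Its log2 levels were also apart for NR4A2 (-2.32), IFITM1 (-4.97), HPGD (1.07), KRT19 (-0.17), CCR3 (-5.50) and STMN2 (-8.37). In other cows the list means apart were cell cycle on 5 mM replicate 2 (0.79), clock on 0 mM replicate 4 (0.064), epithelium on 0 mM replicate 2 (0.80) and mast cells and eosinophils on 0 mM replicate 1 (-0.58). Single genes apart were HAGH (2.61) and SYNM (0.56) on 0 mM replicate 1, COL6A2 (-0.67) on 0 mM replicate 2, FABP5 (0.48) and HLF (-7.10) on 0 mM replicate 3, GATA4 (-1.25) and BPI (-6.18) on 5 mM replicate 3, and HSPA6 (-4.10) on 5 mM replicate 4.

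The array of 5 mM replicate 1 stood apart along the first principal component, which held 57.3% of the variance, and had the array weight 0.194. Whether signal was lost in labelling or hybridization cannot be told from the smooth muscle markers. Of the 14 markers, 12 were brightest on this array, which is part of what sets it apart. A loss over the whole array would also be removed by the scaling to its 75th percentile. Before scaling, that percentile was 1047 intensity units on this array, within the range of 1032 to 1456 over the 8 arrays. Luminal and glandular epithelium markers argue against an effect of 5 mM on every treated cow. Their mean in the other 3 cows given 5 mM differed from that of the 4 given 0 mM by -0.079. This covers that list only. Ciliated epithelium means of 5 mM replicates 2, 3 and 4 were 0.40, -0.46 and 0.57, against 0.23 to 0.82 with 0 mM. The smooth muscle means of these cows were -1.09, 1.46 and -0.86, against -1.51 to 1.21 with 0 mM. A biopsy with more muscle and less epithelium may account for the array. The array's epithelium mean lay below the lowest other array by a difference of -3.31 and its smooth muscle mean was the highest of the 8. These values are part of what sets the array apart, so they are no separate test of this explanation. A response of this cow alone to methylglyoxal stays open and was not tested.

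Of the 63 probes at least 2-fold higher in the 5 mM group at an unadjusted p under 0.05, 22 share 8 or more bases in a row with the telomere repeat CCCTAA, and so do 0 of the 103 lower ones. A set of 22 higher probes that varied in step with r above 0.97 overlaps these, 16 of them sharing 8 bases or more, and both sets were picked for being higher. For genes with a probe in the set in step, or with a matching probe at least 2-fold higher, a difference in their own transcripts is argued against by 26 other probes of 14 genes, with a median of -0.010 (quartiles -0.14 and 0.16), and genomic DNA copied from both strands by 44 probes matching the opposite strand, with a median of 0.0062. Labelled RNA or DNA carrying the repeat is a candidate explanation: the 63 matching probes outside the set in step had a median of 0.19 (quartiles -0.014 and 0.51), and 57 outside both sets a median of 0.17, above the 9 control repeats of the same bases, whose medians lay between -0.029 and 0.081 either way. Whether such RNA differs with methylglyoxal was not tested in other samples.

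The antigen presentation, interferon and cytokine lists share 0 members with the immune cell lists and were lower along with them. With the smooth muscle marker mean as a covariate, the 3 medians kept 40.7%, 49.5% and 50.3% of their values (-0.29, -0.29 and -0.19) and adjusted p values of 7.45e-08, 7.63e-08 and 5.75e-06 in the camera test with a preset correlation, and with the epithelium marker mean they kept 46.2%, 64.6% and 71.1% (-0.33, -0.38 and -0.27), so shares of muscle and epithelium cannot be told apart from other explanations as a part of the shift. With the immune cell marker mean as a covariate, the medians were -0.064, 0.14 and -0.0070 in place of -0.72, -0.59 and -0.38 (adjusted p = 0.389, 0.295 and 0.767 in the same test), the interferon list keeping -23.8% of its value. This was the result set beforehand for fewer immune cells in the biopsies of treated cows, but it cannot decide for them. That marker mean itself ranged from -0.19 to 0.88 with 0 mM and from -0.61 to -0.11 with 5 mM, so it largely followed the dose. As a covariate it also turned the smooth muscle median to -0.92, the epithelium median to 0.090 and the secretory median to 0.097. Of the 13 lists past the preset-correlation threshold, only cell cycle kept its call and direction. Nor does the covariate separate fewer cells from lower expression per cell. A response to methylglyoxal and a difference in biopsy site both stay open, untested.

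Other splits of the 8 arrays into 4 and 4 did not allow chance to be excluded for the 2 counts above 0. They took no account of slide, and with slide as a block the count of probes at least 2-fold apart was 263 in place of 166. At an adjusted p under 0.05 in limma the real split gave 0 probes, which all 35 splits reach of necessity, so that count is no test, and the highest other split gave 6. For probes at an unadjusted p under 0.05 and at least 2-fold apart, the real split gave 166, 19 of the 35 splits gave as many, and the highest other gave 1653. For lists past the preset-correlation threshold the real split gave 13, 8 of the 35 gave as many, the highest other gave 18 and the lowest 4. The 5 splits that put 0 mM replicate 1 with 5 mM replicates 1 and 3, the 3 arrays with the highest smooth muscle means, gave between 1104 and 1653 probes, and the other 29 besides the real one at most 531, which points to a structure of the samples that the doses do not follow.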

How the results depend on the processing

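The marker covariates, the fits without the 3 arrays with the highest smooth muscle means, the fits without repeat-matching probes and the exact permutation of list means were chosen after seeing the data. The count of 0 probes at an adjusted p under 0.05 was 0 under every setting run, also at 0.1 in the main setting, and the smallest adjusted p was 0.0983, without 5 mM replicate 2. The count of 166 probes was 84 with normexp, 361 with no filter on dim probes, 263 with slide as a block, 475 within slide 2 and 538 within slide 3, where the lone array of a group is assumed to vary like the others. Leaving out 1 cow gave 130 to 557. The replicate block gave 352 probes; deviations of same-numbered arrays correlated at 0.40, 0.36, -0.30 and 0.31 for numbers 1 to 4, of which 1, 2 and 4 share a slide, and 6 of the 8 arrays correlated best with their own number. As not every correlation was above 0.1, the numbers were not taken as pairs. The 13 lists were 0 with an estimated correlation, 0 with fry, 0 by exact permutation and 2 with the immune cell covariate, cell cycle and, in the other direction, smooth muscle. The scan date was not run because all arrays were scanned on 1 day.

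Lists past the threshold in either setting reversed as follows. With the immune cell covariate they were 0.14 for interferon, -0.00031 for ribosomal, 0.097 for secretory, 0.090 for epithelium, -0.92 for smooth muscle, 0.23 for T and NK cell and 0.13 for macrophage lists. Without the 3 arrays they were -0.20 for glycation receptors, 0.075 for NRF2, -0.15 for collagens, -0.015 for ciliated cells, where the test turned, and -0.14 for fibroblasts. NRF2 was 0.096 with the epithelium covariate and -0.11 to 0.089 on leaving out 1 cow. Single slides, where no call is made, gave the other sign for the cell cycle median in slide 2, at 0.58, and for the epithelium and fibroblast medians in slide 3, at 0.0087 and -0.39. The cause was not tested. Over all lists and settings, single slides included, 866 values kept direction and side of the threshold, 81 lost the threshold, 48 gained it, and 115 had the other sign without a call in either setting, as had 69 values of named genes. Of the 137 named genes, 89 had the same sign under every setting, among them the 24 lead genes, whose choice without overlap largely fixes it. Of those 24, 13 were smaller by over 1.5 times with normexp and 12 with the immune cell covariate, where STAT5A was 0.27. Probes not well above background limit what low genes can show.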

Other observations

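No test was run for the values in this part, which were picked after they were seen. Adipocyte and stromal fibroblast markers, like those of smooth muscle, were highest on 5 mM replicate 1, at 1.20 and 0.60 against at most 0.51 and 0.16 on the other 7 arrays. Endothelial markers, at -0.55, and Schwann cell and neuron markers, at -1.31, were lowest there, against at least -0.16 and -0.33. Erythrocyte and platelet markers spanned -1.26 to 1.32 over the other arrays.

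The 3 probes of GLO1, the glyoxalase I gene, spanned 3.91, 1.09 and 1.24 on the log2 scale over the 8 cows, in order of their positions from 12988895 on chromosome 23, and their differences between doses were -0.32, 0.19 and -0.24. The named probe of NDUFS1, a gene of respiratory complex I, was between 1.97 and 2.17 on 5 arrays and at -0.29 and -0.21 on 0 mM replicates 2 and 3, with no value on 5 mM replicate 2.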
